A study of Danio rerio with 40 samples.

How the data were processed

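Whole brains of zebrafish aged 6 months were profiled by RNA sequencing of polyA RNA. The fish were siblings, either heterozygous or homozygous for the naglu allele A603fs, and each had received an intraperitoneal injection of 10 µg ferric citrate in 0.85% saline, or of saline alone, 7 days before. Per the labels' protocols, whole heads were kept in RNAlater, brains were dissected from them, and libraries were made with a polyA mRNA kit. Each library is a different fish, so replicate numbers only name libraries. The 40 libraries fall into 4 groups of 10 by the genotype and treatment in the labels. The labels also give sex and 1 of 5 home tanks for every fish, and a number as its title, here called the fish number, whose meaning is not given in the sources used here.

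The deposited values are raw counts per Ensembl gene, whole numbers for 32057 genes in each library. Per the submitters' processing notes, fastp, STAR, UMI-tools and featureCounts and the build GRCz11 were used. Their versions, roles, settings, strand handling and annotation release are not given in the sources used here. Whether duplicate molecules were removed is therefore not known. Reads from overlapping or antisense genes cannot be told apart, and values of near-identical paralogs are uncertain. All 40 columns of the table were used. Library totals ran from 11800000 to 38500000 counts with a median of 26900000. Over the 780 pairs of libraries no pair was identical, and the smallest chi-square per degree of freedom was 6.96, so no library was treated as a copy of another.

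Gene symbols came from a table of gene IDs and symbols that matched 28988 of the 32057 genes (90.4%). This table often lacks the paralog letter, and 3103 tested genes share a symbol with another gene, so such genes are given with their Ensembl ID. Chromosomes were taken by symbol from RefSeq's gene table on the assembly GRCz12tu, which differs from the build of the counts. They were used only to ask which genes share the chromosome of naglu, and no coordinates are given.

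Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, which left 19668, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 40 libraries with a mean per group and terms for sex and home tank, 9 coefficients in all and 31 residual degrees of freedom. Contrasts gave 8 comparisons, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 on the adjusted p. Fold changes are log2 values from this fit with their standard errors (SE). Expression levels are log2 CPM, counts scaled to the TMM-adjusted library total, with a prior count of 2.

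The design, the tests, 32 gene lists, the rule for naming genes and 17 alternatives per comparison were chosen before the data were examined. For each comparison the rule names naglu, up to 12 called genes with the largest rise and up to 12 with the largest fall whose mean log2 CPM was at least 1 and whose symbol is a gene name, and up to 4 called members of each list by smallest p. Where no gene was called, the 5 genes with the smallest p are given as not passing. Called genes on the chromosome of naglu are named as such. Some genes that the rule names are not reported here, while counts and list tests include them. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Members were also counted after adjustment over the list alone. Enrichment of called genes on the chromosome of naglu was tested with Fisher's exact test, two-sided.

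The fitting step was tested on simulated counts for the 19668 genes with 50 genes changed at each of 4 fold sizes. For homozygous against heterozygous saline fish 68% of 1.5-fold and 86% of 2-fold changes were recovered, and 10 unchanged genes were called. For iron against saline the share was 66% and 90% in heterozygous fish and 74% and 84% in homozygous fish. For the interaction it was 34% and 78%. Simulated genes were independent of each other and carried no effect of sex, tank or fish number, so recovery in the real data may be lower.

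Alternatives covered other size factors, other filters on low counts, DESeq2 1.42.0, limma voom, other covariates, 1 surrogate variable from sva 3.50.0, fewer libraries and fewer genes. Chosen after seeing the data were a spline of fish number, fish numbers up to 40 or above 40 alone, and fits without the libraries labelled heterozygous saline 10, heterozygous saline 5 or heterozygous iron 5. List scores were also compared with each library left out in turn, chosen after the scores were seen. A genotype score was also chosen after seeing the data. For each library, the other 39 were used to estimate the genotype difference of the 50 genes that separate the genotypes best, with treatment, sex and tank in the model, and the library was placed on that difference, with 0 for heterozygous and 1 for homozygous. Permutation tests of scores and correlations used 100000 draws and are two-sided.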

Results

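The data are counts per gene from 40 whole brains, 10 in each of 4 groups: heterozygous saline, heterozygous iron, homozygous saline and homozygous iron. Homozygous naglu mutants model mucopolysaccharidosis type IIIB, a lysosomal storage disease in which heparan sulfate is not broken down, and they were compared with their heterozygous siblings. Mean library totals were 25700000 counts ± 8270000 (SD, n = 10) in heterozygous saline fish, 30200000 ± 6460000 in heterozygous iron fish, 22100000 ± 4620000 in homozygous saline fish and 25000000 ± 8860000 in homozygous iron fish, and ran from 11800000 to 38500000 in single libraries. Females made up 2, 5, 7 and 5 of the 10 fish in these groups, in the same order, and sex and home tank were terms of the model behind each fold change.

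The targeted gene naglu, which encodes alpha-N-acetylglucosaminidase, was counted at similar levels in all 4 groups. Its mean log2 CPM was 1.85 ± 0.36 (SD, n = 10) in heterozygous saline fish, 1.97 ± 0.34 in heterozygous iron fish, 2.07 ± 0.33 in homozygous saline fish and 1.99 ± 0.34 in homozygous iron fish. The log2 fold change of homozygous over heterozygous fish was 0.22 (SE 0.19, edgeR adjusted p = 0.60) after saline and 0.05 (SE 0.18, adjusted p = 0.97) after iron. Counts per gene do not separate the mutant from the normal transcript, so the level of naglu does not check the genotype labels. The level did differ with fish number, with a log2 fold change of -0.59 (SE 0.07, adjusted p = 2.7e-07) in the 20 fish numbered above 40 relative to the 20 numbered up to 40.

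The comparison of homozygous with heterozygous saline fish asks what loss of naglu changes without added iron. Of 86 lysosome genes 20 rose and of 28 myelin genes 9 fell, and neither list passed with an estimated correlation (adjusted p = 0.317 for each). Among genes with a mean log2 CPM of at least 1, the largest rises were in pmelb, which encodes a melanosome matrix protein, by 2.53 on the log2 scale (SE 0.41, fold 5.76, n = 10 per group, edgeR adjusted p = 0.0019). Next were capg (ENSDARG00000099672), an actin-capping protein, by 1.80 (SE 0.36), and the complement gene c4b by 1.70 (SE 0.36). The zinc transporter slc30a8 rose by 1.54 (SE 0.31), gpd1c by 1.3 (SE 0.24), the progranulin gene grna by 1.25 (SE 0.31) and gnsb, which encodes another enzyme of heparan sulfate breakdown, by 1.13 (SE 0.21). The largest falls among these were in the titin gene ttn (ENSDARG00000000563) with a log2 fold change of -1.67 (SE 0.39), mybphb with -1.26 (SE 0.23), the tubulin gene tuba8l5 with -1.05 (SE 0.17) and the complement gene c7b with -1.0 (SE 0.26). The chemerin receptor gene cmklr1 (ENSDARG00000090890), tspan36, nupr1b, agtrap and hs1bp3 rose by 1.03 to 1.3, all with an adjusted p under the threshold. The genes sall1 (ENSDARG00000075891), angpt2b, tmem125, cass4, arhgap28 and ap1m3 passed likewise, with log2 fold changes from -0.90 to -0.79.

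**Figure D1:**
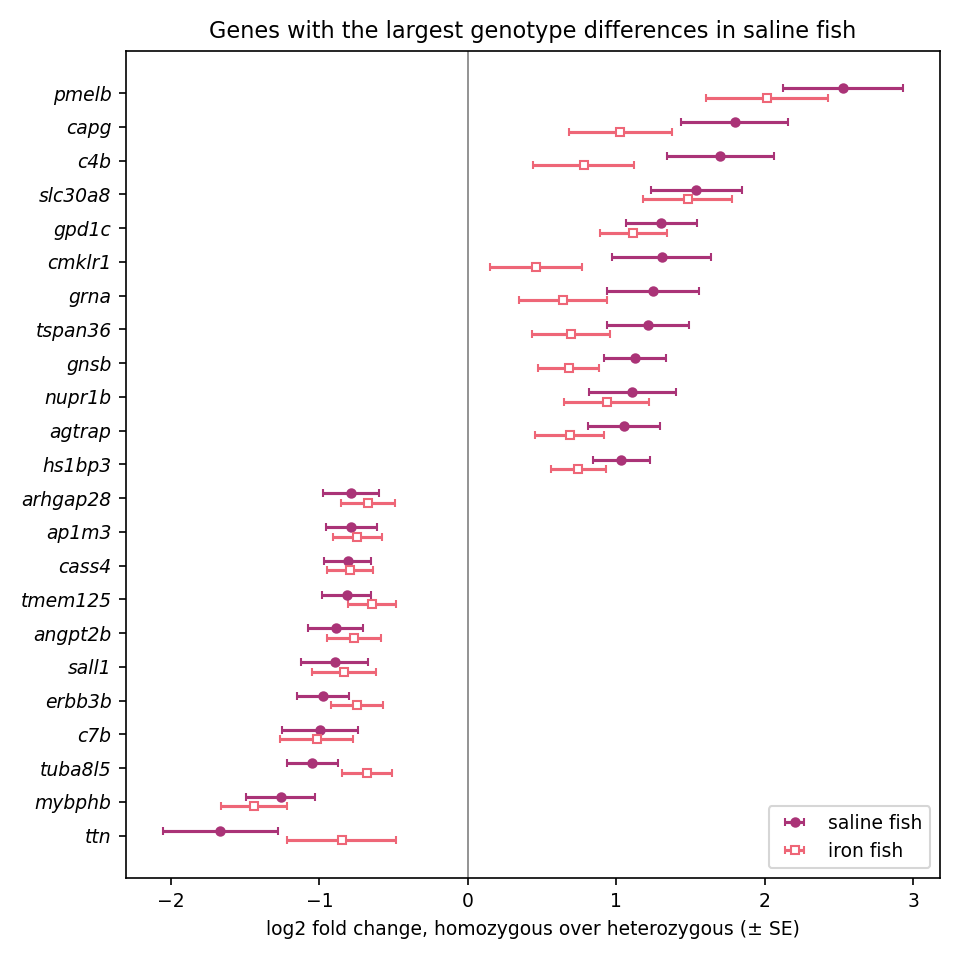
Log2 fold change of homozygous over heterozygous fish (x axis, with SE) for the 12 genes that rose most and 11 of the 12 that fell most in saline fish among those with a mean log2 CPM of at least 1 (y axis), in saline fish (filled circles) and iron fish (open squares), n = 10 per group. Each gene has the same sign after saline and after iron, from pmelb at 2.53 and 2.01 to mybphb at -1.26 and -1.44.

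In all, 112 genes rose and 134 fell, 246 of the 19668 tested, at edgeR's adjusted threshold. At an unadjusted p under 0.05 there were 3002 genes, where chance gives 983. The libraries labelled heterozygous saline 5 and heterozygous iron 5 had genotype scores of 1.18 and 1.23, within the range of 0.71 to 1.23 of the 20 homozygous libraries and above the -0.41 to 0.33 of the other 18 heterozygous libraries. Without both, 586 genes were called, among them all 246. Leaving out libraries chosen for lying on the homozygous side of the same difference can raise the count by itself. Wrong genotype labels would raise it too, so the rise does not tell these apart. With 1 surrogate variable in the model 26 genes were higher and 74 lower, 100 in all and 83 of them among the 246. With a spline of fish number 147 were higher and 120 lower, 267 in all and 200 of them among the 246. With males alone 0 were called by edgeR, with females alone 0, and with only the 20 saline libraries 3.

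**Figure D2:**
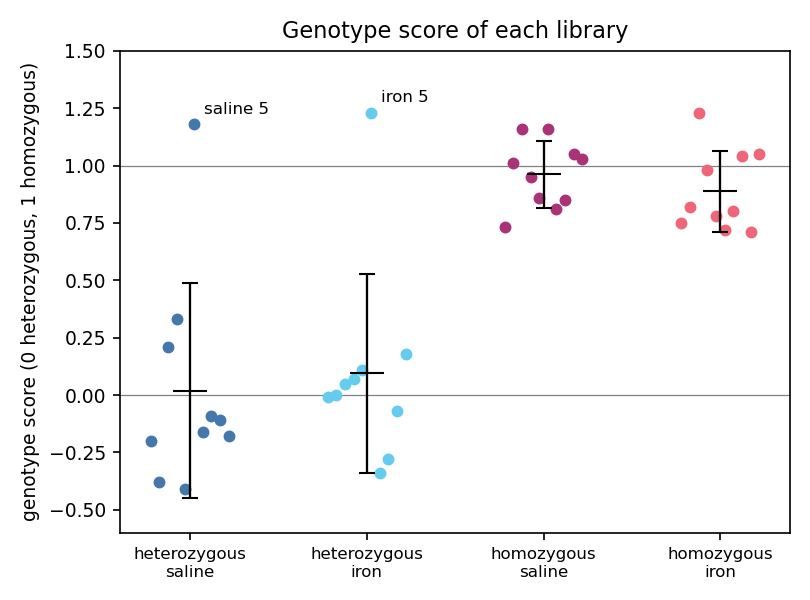
Genotype score (y axis, no unit, 0 heterozygous and 1 homozygous) of each library (points) in the 4 groups (x axis), each from a model of the other 39 libraries, with the group mean and SD (black bars, n = 10). The libraries labelled heterozygous saline 5 (1.18) and heterozygous iron 5 (1.23) lie among the homozygous libraries.

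Of 86 measured lysosome genes, 20 rose and 0 fell after saline, 38 rising and 1 falling when adjusted over the list alone. The subunits of beta-hexosaminidase rose, hexb by 0.61 (SE 0.11, adjusted p = 0.005) and hexa by 0.58 (SE 0.11, adjusted p = 0.0074), and the mannosidase gene man2b2 by 0.57 (SE 0.11). The median log2 fold change of the list was 0.225, with a camera adjusted p of 3.23e-20, an adjusted p = 0.317 with an estimated correlation, and a fry adjusted p of 0.0131. Of 28 oligodendrocyte and myelin genes, 9 fell and 0 rose, 17 falling and 1 rising when adjusted over the list alone. The neuregulin receptor gene erbb3b changed by -0.98 (SE 0.18, adjusted p = 0.005), the lineage factor sox10 by -0.64 (SE 0.13) and tspan2 by -0.38 (SE 0.08). The list median was -0.39, with a camera adjusted p of 1.02e-08, an adjusted p = 0.317 with an estimated correlation, and a fry adjusted p of 0.0217.

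**Figure D3:**
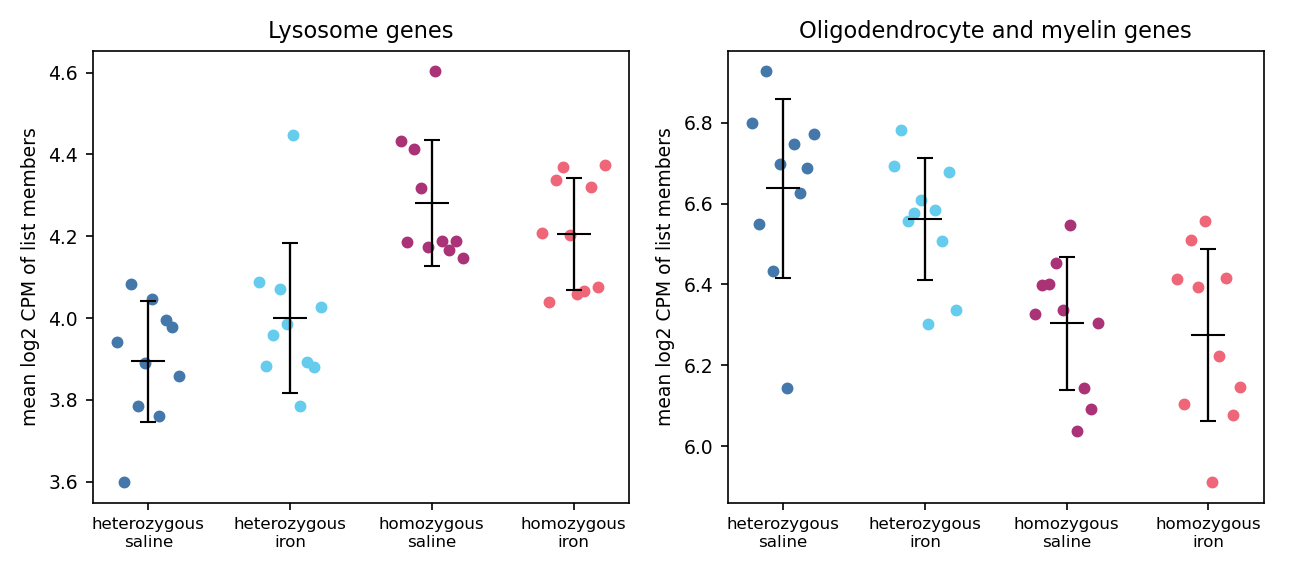
Mean log2 CPM (y axis) over the 86 lysosome genes (left) and the 28 oligodendrocyte and myelin genes (right) in each library (points) of the 4 groups (x axis), with the group mean and SD (black bars, n = 10). After saline the lysosome mean was 4.28 ± 0.15 in homozygous and 3.89 ± 0.15 in heterozygous fish, and the myelin mean 6.30 ± 0.16 and 6.64 ± 0.22.

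Markers of other cells were measured in the same saline fish. Of 49 microglia and macrophage genes, hexb and grna rose, and both are also on the lysosome list counted above. When adjusted over the list alone 23 rose, and the median log2 fold change was 0.618. The camera call (adjusted p = 1.15e-14) was lost, with an adjusted p = 0.362 with an estimated correlation. The median was 0.191 with male libraries only (camera adjusted p = 0.0362) and 0.366 in fish above 40, and the saline groups hold 7 and 2 females. The 27 interferon response genes had a median of 1.297 with 0 called by edgeR, 0 also when adjusted over the list alone, and an adjusted p = 0.479 with an estimated correlation. The median of this list was 0.389 with males alone (camera adjusted p = 0.583). The 25 antigen presentation genes had a median of 0.471, 0 called and 10 rising when adjusted over the list alone, with an adjusted p = 0.362 with an estimated correlation, and a median of 0.187 with male libraries only (camera adjusted p = 0.114). Of 51 iron homeostasis genes, hif1aa rose by 0.76 (SE 0.15, adjusted p = 0.0068) and hephl1a by 0.36 (SE 0.09, adjusted p = 0.033), also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.248). The 34 glutamatergic neuron genes had a median of -0.099 with 0 called, 0 also when adjusted over the list alone, and an adjusted p = 0.508 with an estimated correlation. The 24 GABA neuron genes had a median of -0.174 with 0 called, 0 also when adjusted over the list alone, an adjusted p = 0.317 with an estimated correlation and a fry adjusted p of 0.0367. The 46 synapse genes had a median of -0.126 with 0 called, 0 also when adjusted over the list alone, a camera adjusted p of 1.2e-05 and an adjusted p = 0.496 with an estimated correlation. The 41 autophagy genes had a median of -0.077 with 0 called, 1 rising and 1 falling when adjusted over the list alone, an adjusted p = 0.362 with an estimated correlation and a fry adjusted p of 0.0367. The lymphocyte gene ccr9 (ENSDARG00000055186) rose by 2.30 (SE 0.55, adjusted p = 0.027), 1 of 11 lymphocyte genes both over all genes and when adjusted over the list alone, and that list did not pass (camera adjusted p = 0.247). Camera also called 6 other lists after saline, and none of these passed with an estimated correlation. The 81 ribosomal protein genes had a median of 0.127, with 80 of them higher (camera adjusted p = 5.48e-13, adjusted p = 0.508 with an estimated correlation). The 30 astroglia genes had a median of 0.191, with 24 higher (camera adjusted p = 0.00173, adjusted p = 0.592 with an estimated correlation), and the 35 endothelium and mural genes 0.105, with 26 higher (camera adjusted p = 0.0324, adjusted p = 0.737 with an estimated correlation). These medians were 0.124 (camera adjusted p = 0.0113) and 0.06 (camera adjusted p = 0.239) without the library heterozygous saline 10, which was low for both lists. The 36 ferroptosis and redox genes had a median of 0.098, with 3 rising when adjusted over the list alone (camera adjusted p = 0.00031, adjusted p = 0.362 with an estimated correlation). The 37 unfolded protein and stress response genes had a median of 0.061 (camera adjusted p = 0.012, adjusted p = 0.362 with an estimated correlation). In these 5 lists 0 genes were called by edgeR, and 0 when adjusted over the list alone except those 3. Of 32 inflammatory cytokine and complement genes, c4b rose and c7b fell, 2 rising and 1 falling when adjusted over the list alone. The list median was 0.178 (camera adjusted p = 0.00564, adjusted p = 0.508 with an estimated correlation). With fish numbers up to 40 only, it was -0.011 and that of the astroglia genes -0.002.

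After iron, homozygous and heterozygous fish differed in part of the same genes. The comparison asks what loss of naglu changes in fish given iron. The gene pmelb rose by 2.01 (SE 0.41, n = 10 per group, edgeR adjusted p = 0.025), slc30a8 by 1.48 (SE 0.30), gpd1c by 1.11 (SE 0.23) and hif1aa, a subunit of a hypoxia-inducible transcription factor, by 0.74 (SE 0.14). The lysosomal enzymes hexb, man2b2 and ctsd rose by 0.57 (SE 0.11), 0.51 (SE 0.11) and 0.37 (SE 0.07), and pepd, hps4 and slc12a9 by 0.33 to 0.46. Among genes with a mean log2 CPM of at least 1, falls were largest in mybphb with a log2 fold change of -1.44 (SE 0.22, adjusted p = 0.0021) and crp1 with -0.86 (SE 0.18). The myelin gene mag changed by -0.45 (SE 0.09), and cass4, ninj2, htra1 (ENSDARG00000032831), cd226, tppp (ENSDARG00000105029) and cdk15 by -0.79 to -0.31.

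In all, 13 genes rose and 14 fell after iron, 27 called by edgeR, and 1637 had an unadjusted p under 0.05. DESeq2 called 141, voom 229, edgeR with 1 surrogate variable 72 and edgeR with only the 20 iron libraries 1. With males alone 36 were called, 33 higher and 3 lower, 11 of them among the 27, and with a spline of fish number 17 were higher and 59 lower. Without the libraries labelled heterozygous saline 5 and heterozygous iron 5, 196 genes were called, among them all 27. Again, how the libraries were chosen can raise this count by itself. Of the 86 lysosome genes 3 rose, 19 when adjusted over the list alone, and the median was 0.16 (camera adjusted p = 1.43e-16, adjusted p = 0.361 with an estimated correlation). Of the 28 myelin genes 2 fell, 13 when adjusted over the list alone, and the median was -0.298 (camera adjusted p = 9.48e-10, adjusted p = 0.361 with an estimated correlation). With fish numbers up to 40 only the myelin median was -0.078, and camera no longer called the list. The 49 microglia genes had a median of 0.119, and the list did not pass (camera adjusted p = 0.224). Of these, hexb was called, which is also on the lysosome list, and 1 rose when adjusted over the list alone. The microglia median was 0.464 with male libraries only (camera adjusted p = 1.1e-07) and 0.2 with a term for fish-number band (camera adjusted p = 0.00426). It was 0.235 with a spline of fish number (camera adjusted p = 0.0216) and 0.258 without heterozygous iron 5 (camera adjusted p = 0.00271). The 46 synapse genes had a median of -0.078 (camera adjusted p = 0.000907, adjusted p = 0.791 with an estimated correlation) and medians of 0.022 and 0.016 with fish numbers up to 40 only and with fish numbers above 40 only. The 25 antigen presentation genes had a median of 0.222 (camera adjusted p = 0.0237, adjusted p = 0.815 with an estimated correlation) and the 82 nuclear oxidative phosphorylation genes 0.052 (camera adjusted p = 2.25e-05, adjusted p = 0.805 with an estimated correlation). The antigen presentation median was -0.118 with fish numbers up to 40 only and 0.58 with male libraries only. In the synapse, antigen presentation and oxidative phosphorylation lists 0 genes were called by edgeR and 0 when adjusted over the list alone. The glutamatergic and GABA neuron lists did not pass (medians -0.052 and -0.06, camera adjusted p = 0.068 and 0.104), but were called with male libraries only (-0.095 and -0.071, camera adjusted p = 0.00053 and 0.0186). The 19 photoreceptor, lens and pineal genes had a median of 0.895 with 0 called and 0 when adjusted over the list alone (camera adjusted p = 0.000702, adjusted p = 0.791 with an estimated correlation). In fish up to 40 their median was 0.074 (camera adjusted p = 0.73). The mean log2 CPM of these genes was 1.21 to 2.93 in 11 of the 40 libraries and -0.39 to 0.24 in the other 29. The 11 were 3 heterozygous saline, 1 heterozygous iron, 3 homozygous saline and 4 homozygous iron libraries.

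The genotype differences after saline and after iron, which share no library, were set against each other. Both came from the same fit with common terms for sex and tank and a common estimate of the spread. They are therefore not fully independent, since errors in these terms enter both. Of the 246 genes called after saline, 245 (99.6%) had the same sign after iron, against 66% of all 19668 genes, with a median ratio of the iron to the saline change of 0.633. All 27 genes called after iron had the same sign after saline, with a median ratio of the saline to the iron change of 1.02. Changes of genes picked for passing a threshold shrink in other fish by selection alone. In both lists were 24 genes, among them pmelb, slc30a8, hexb and mybphb, all in the same direction, where independent lists share 0.34. Across the 19668 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.54 and Spearman's rho 0.427, and r was 0.673 without both doubted libraries, which were chosen on the same genotype difference.

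Averaged over both treatments, 399 genes rose and 448 fell in homozygous fish, 847 in all. Upper quartile factors gave 466 higher and 379 lower, and 1 surrogate variable 206 higher and 374 lower, 580 in all and 431 of them among the 847. Among genes with a mean log2 CPM of at least 1, the largest rises were pmelb (2.27, SE 0.28), the scavenger receptor gene marco of macrophages (1.51, SE 0.33, adjusted p = 0.0052) and slc30a8 (1.51, SE 0.20). The largest falls were mybphb (-1.35, SE 0.16) and ttn (-1.26, SE 0.26). Of the 86 lysosome genes 32 rose, 47 rising and 1 falling when adjusted over the list alone, with an adjusted p = 0.149 with an estimated correlation. Of the 28 myelin genes 16 fell, 18 falling and 3 rising when adjusted over the list alone, with an adjusted p = 0.149 with an estimated correlation, and fry gave an adjusted p of 0.000711 for each of these lists. Among 51 iron homeostasis genes hif1aa (0.75, SE 0.10), hephl1a (0.30, SE 0.06), the ferritin gene fthl27 (0.25, SE 0.06) and the heme oxygenase gene hmox1 (0.56, SE 0.14) rose and 1 gene fell, 5 rising and 1 falling when adjusted over the list alone. Without both doubted libraries, chosen on this difference, 1637 genes were called, 893 higher and 744 lower and 834 of them among the 847. With females alone 0 were called by edgeR, and with males alone 122.

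Genes linked to naglu can differ between siblings through the haplotype around the mutation. After saline 7 of 222 called genes with a known chromosome lay on that of naglu: rala (-0.42, SE 0.09), cd226 (-0.68, SE 0.14), cst14a.2 (0.45, SE 0.10), arhgap28, abcd4 (0.48, SE 0.12), crp1 (-0.74, SE 0.18) and nub1 (0.83, SE 0.21). That is 3.15% against 2.22% of the genes tested, with an odds ratio of 1.44 (Fisher's exact p = 0.351, adjusted p = 0.351). After iron 3 of 25 lay there, crp1, cd226 and si:ch211-234p6.5 (-0.67, SE 0.14), with an odds ratio of 6.05 (Fisher's exact p = 0.0173, adjusted p = 0.0519 over the 3 genotype comparisons).

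Ferric citrate changed no gene past the threshold in either genotype, in the comparison that asks what iron alone does. The transferrin receptor genes tfr1a and tfr1b had log2 fold changes of iron over saline of -0.13 (SE 0.28) and -0.48 (SE 0.23) in heterozygous fish and of -0.41 (SE 0.32) and -0.21 (SE 0.26) in homozygous fish, n = 10 per group. For tfr2 they were 0.10 (SE 0.29) and 0.02 (SE 0.33). Of the 51 iron homeostasis genes 0 were called by edgeR in either genotype, 0 when adjusted over the list alone, and the list medians were -0.036 (camera adjusted p = 0.582) and -0.009 (camera adjusted p = 0.477). The smallest p-values in heterozygous fish, none passing, belonged to bbs12 (0.39, SE 0.10), si:ch211-199g17.9 (-0.65, SE 0.17), aar2 (0.37, SE 0.10), aplnrb (-0.22, SE 0.06) and ubxn10 (-0.63, SE 0.18). In homozygous fish they belonged to gria4a (0.23, SE 0.06), ENSDARG00000112767 (0.27, SE 0.07), pof1b (-0.57, SE 0.16), nmu (-0.55, SE 0.15) and dhx36 (0.15, SE 0.04).

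The count was 0 by edgeR, by DESeq2 and by voom in heterozygous fish, in homozygous fish and in both averaged, and without both doubted libraries 0 by edgeR. At an unadjusted p under 0.05 edgeR gave 662, 287 and 376 genes, below the 983 that chance gives. Camera called 8 lists in heterozygous and 5 in homozygous fish, and with an estimated correlation 0 in each. The microglia list was among both, but the smallest camera adjusted p in homozygous fish, 4.6e-17, belonged to another list. In heterozygous fish the 49 microglia genes had a median of 0.35 with 0 called and 0 when adjusted over the list alone (camera adjusted p = 2.2e-12, adjusted p = 0.876 with an estimated correlation). Heterozygous saline 10 was low and heterozygous iron 5 high for these genes, and the median was 0.268 without the first, 0.271 without the second and 0.148 without both (camera adjusted p = 0.0157). In homozygous fish the median was -0.122, likewise with 0 called and 0 when adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.967 with an estimated correlation). With males alone the median in heterozygous fish was 0.454 (camera adjusted p = 9.53e-11), from 8 saline and 5 iron males. In homozygous fish it was 0.716 with males alone, from only 3 saline and 5 iron males.

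The interaction asks whether the response to iron differed between genotypes, and no gene passed. The 5 smallest p-values belonged to bbs12 (-0.59, SE 0.14), zdhhc11b (0.73, SE 0.19), ENSDARG00000112767 (0.38, SE 0.10), ENSDARG00000112040 (0.66, SE 0.18) and trpc7 (ENSDARG00000079469, 0.68, SE 0.19). edgeR, DESeq2 and voom each called 0, and 498 genes had an unadjusted p under 0.05 by edgeR. Among the 246 genes called between genotypes after saline the interaction called 0 when adjusted over these alone, with 22 at an unadjusted p under 0.05 and a smallest adjusted p of 0.121. The difference between 246 and 27 called genes is therefore not shown to be a difference in effect. The 49 microglia genes had a median interaction of -0.494 with 0 called and 0 when adjusted over the list alone (camera adjusted p = 1.31e-12, adjusted p = 0.803 with an estimated correlation). Their median was -0.234 without heterozygous saline 10 and heterozygous iron 5, and 0.258 with males alone, the opposite sign. The fit with males alone rests on only 3 homozygous saline fish.

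Expression also followed the fish number, for which the main model has no term. Fish number and home tank were related: the numbers ran through tanks 1 to 5 in order from 2 to 40, and again from 41 to 79. The tank term can therefore take up part of a trend with fish number. Of 19668 genes, edgeR called 4201 between fish numbers above 40 and up to 40, and 2898 with a spline of fish number. The fish number is spread over the 4 groups with means of 43.7 ± 28 (SD, n = 10), 41.2 ± 15, 37.7 ± 24 and 46.3 ± 31 in heterozygous saline, heterozygous iron, homozygous saline and homozygous iron fish. The clock gene ciarta had a mean log2 CPM of 5.8 ± 0.36 (SD, n = 10) in the fish with the 10 lowest numbers and 3.03 ± 0.30 in those with the 10 highest. Across the 40 fish its Pearson's r with fish number was -0.96 and Spearman's rho -0.97 (permutation p = 1e-05 for each, the smallest these draws can give, adjusted p = 1.2e-05 for r over 35 clock genes). Without the 2 farthest fish r was -0.96, and it was -0.89 in fish up to 40 and -0.85 above 40. For nfil3-5 r was 0.95 and rho 0.95 (permutation p = 1e-05 for each, adjusted p = 1.2e-05 for r), 0.94 without the 2 farthest fish, 0.66 up to 40 and 0.95 above 40. In a limma model with group, sex, tank and fish number, 29 of the 35 measured clock genes passed, 11 rising and 18 falling with fish number, and 0 of them were called between genotypes or treatments by edgeR, also when adjusted over the list alone.

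**Figure D4:**
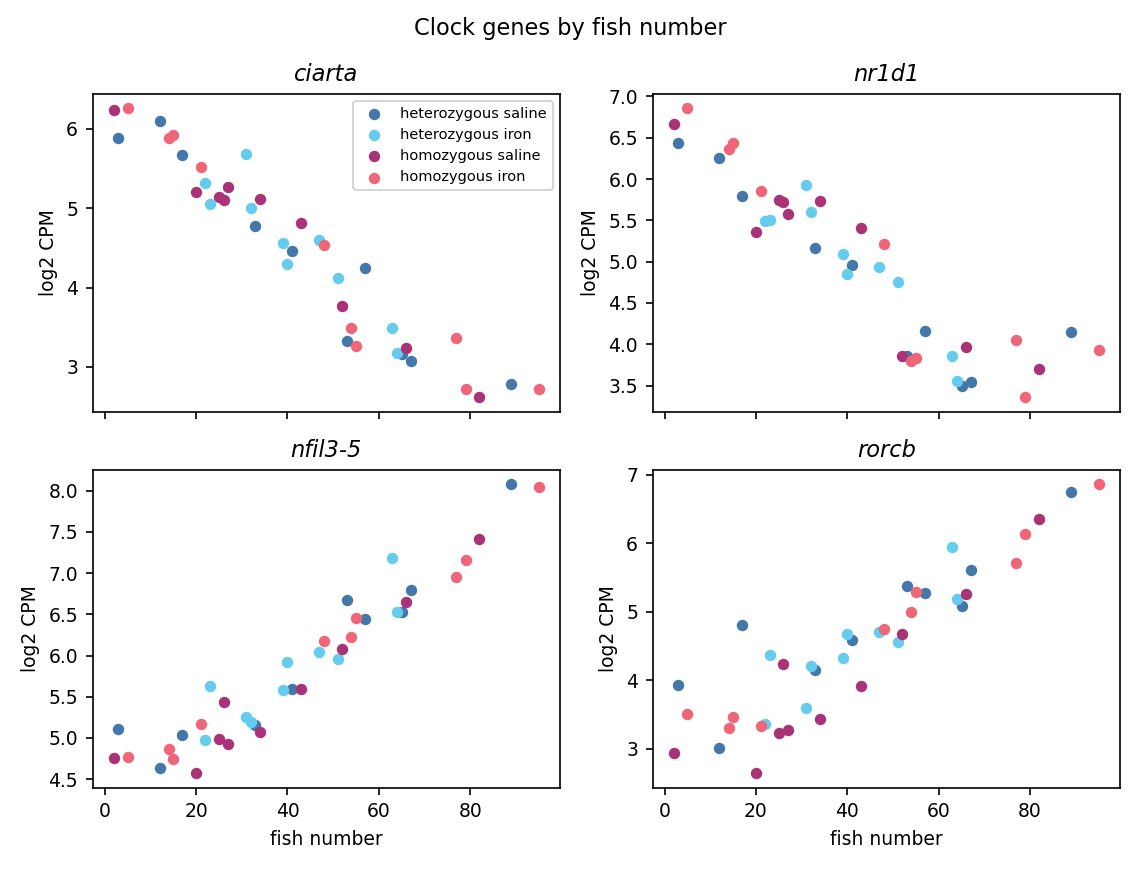
Log2 CPM (y axes) of the clock genes ciarta, nr1d1, nfil3-5 and rorcb against fish number (x axes) in the 40 libraries, coloured by group. Over the 40 libraries, the correlation with fish number is negative for ciarta (r = -0.96) and nr1d1 (r = -0.91) and positive for nfil3-5 (r = 0.95) and rorcb (r = 0.91).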

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

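The tests by sex, mislabelling, swap, mixing, a step in fish number and time of day below were chosen after the patterns were seen, as were the genotype score and the libraries left out, and the splits and the test of library size were chosen before their results. Tests of whether the lower myelin score follows from sex, dilution or sampling order, and of whether the library labelled heterozygous saline 10 explains 246 against 27 calls, were also run after the patterns were seen, and only their values are given.

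Within-group outliers were sought with Dixon's ratio, the gap of the most extreme library to the nearest other divided by the range of its group of 10. Among 316 tests of the named genes, gene lists and library measures 51 passed, where chance flags about 1 in 20 groups, or 16. Many named genes were chosen for differing between genotypes, and lists share members such as hexb and grna. The tests are therefore not independent, and 1 unusual library can pass many of them, so the excess over 16 is not a count of separate outliers. The library labelled heterozygous iron 5 gave 20 of the 51. It was high for pmelb (0.488), c4b (0.512), grna (0.475), gnsb (0.467), hs1bp3 (0.478), hexb (0.527), man2b2 (0.704), ctsd (0.633) and the lists of lysosome (0.543), microglia (0.477), inflammatory (0.476) and iron homeostasis genes (0.475). It was low, among others, for mybphb (0.604), c7b (0.674), angpt2b (0.547), cass4 (0.563), ap1m3 (0.659), ninj2 (0.526) and htra1 (0.577). The library labelled heterozygous saline 5 gave 7, low for mybphb (0.576), tuba8l5 (0.471), erbb3b (0.534), sall1 (0.506), ap1m3 (0.561) and cd226 (0.505) and high for hps4 (0.467).

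These libraries carry the pattern of homozygous fish, with genotype scores of 1.23 (heterozygous iron 5) and 1.18 (heterozygous saline 5), where the other 18 heterozygous libraries reach 0.33. A swap with a homozygous library of the series is argued against by the score of 50 genes. Its lowest homozygous value was 0.71, above every other heterozygous library. With 10 genes on the chromosome of naglu, homozygous iron 1 scored 0.29 (0.75 with 50 genes). That lies within the -0.6 to 0.33 of the other heterozygous libraries, so the score of 10 genes cannot decide on a swap with this library. An equal mix of RNA of both genotypes is argued against, since the lower score of the 2 doubted libraries was 1.18 and a mix needs about 0.5. A wrong genotype label, without a partner in the series by the score of 50 genes, may account for the pattern. With 10 genes on the chromosome of naglu the lower score of the 2 doubted libraries was 1.07. This is within the 0.29 to 1.36 of homozygous libraries and above the highest other heterozygous score of 0.33. A heterozygous fish in a state like that of homozygous fish stays open, since enrichment of called genes on that chromosome did not pass after saline (odds ratio 1.44, adjusted p = 0.351) or iron (6.05, Fisher's exact p = 0.0173, adjusted p = 0.0519, and 2.38, Fisher's exact p = 0.018, unadjusted, for the 200 genes of smallest p), and neither library was relabelled.

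Fewer genes were called between genotypes after iron (27) than after saline (246). That the saline calls are sex differences is argued against, since 99.6% of them, against 66% of all genes, kept their sign in the iron groups, which have 5 females each. Whether the unequal sexes set the number of calls stays open: with males alone the counts were 36 after iron and 0 after saline, the opposite order, but the saline groups hold only 8 and 3 males. The 2 doubted libraries do not account for all of it, since the saline count was still 2.99 times the iron count without both. That ratio, from 586 and 196 calls, was smaller than the ratio of 246 to 27. It was smaller also without heterozygous iron 5 alone, with 376 and 149 calls. Each count can rise by how these libraries were chosen. Without the library labelled heterozygous saline 10 the counts were 183 and 34. Chance in how fish were divided between treatments may account for it: 46 of 100 such divisions within genotype, the real one included, gave a difference in calls of at least 219. The highest of the others was 1866, and what sets the size of these differences was not tested.

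Clock genes followed fish number. A step between fish numbers up to 40 and above 40 is argued against as the whole cause, since 19 of 35 clock genes passed with the step in the model. Among these, nr1d4a passed only with the step (limma adjusted p = 0.0063, and 0.072 without it). Library size is argued against, since 29 passed with the log2 total count in the model. Time of day at sampling may account for it: by the sign of the slope, passing or not, 11 genes driven through E-boxes had negative and 3 positive slopes, against 0 and 3 driven through ROR elements (Fisher's exact p = 0.029), and among those that passed, counted later, 10 fell and 1 rose against 0 and 2 (Fisher's exact p = 0.038). That match missed genes whose symbols lack the paralog letter, and with bmal1, clock and nr1d2 added after 0.029 was seen the slopes were 12 and 3 against 0 and 7 (Fisher's exact p = 7e-04), with 11 and 1 against 0 and 6 that passed (Fisher's exact p = 0.00038). Fisher's test takes genes as independent, but these include paralogs and were measured in the same 40 fish, so its p-values may be too small. Sampling times are not given in the sources used here, and no biological explanation was tested.

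Other outliers are given as values. The library labelled heterozygous saline 10 was low for grna (0.541), tspan36 (0.526) and the lists of heparan sulfate proteoglycan (0.479), microglia (0.61), astroglia (0.614), endothelium (0.493) and neutrophil genes (0.533). Heterozygous saline 2 was high for the mitochondrial genome list (0.498), the percent of mitochondrial counts (0.533) and the percent in the 10 highest genes (0.718). Heterozygous saline 3 was low for nuclear oxidative phosphorylation genes (0.544), and heterozygous saline 9 was high for skeletal muscle genes (0.522). Heterozygous iron 1 was high for photoreceptor, lens and pineal genes (0.82), as were 10 libraries of the other 3 groups, which spread too widely there to pass the ratio. Heterozygous iron 9 was low for cholesterol synthesis genes (0.492). Homozygous saline 1 was high for pmelb (0.525) and endothelium genes (0.473) and low for nuclear oxidative phosphorylation genes (0.561), and homozygous saline 4 was high for the percent of mitochondrial counts (0.478). Homozygous saline 5 was high for sall1 (0.628) and cd226 (0.502). Homozygous iron 2 was low for hs1bp3 (0.51), homozygous iron 3 was high for nupr1b (0.512), and homozygous iron 9 was high for hephl1a (0.661) and lymphocyte genes (0.587).

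The genotype effect differed between treatments by camera's interaction test for 8 lists, none of them with an estimated correlation (smallest adjusted p = 0.80). The median interactions were -0.065 for lysosome, 0.05 for autophagy, -0.494 for microglia, -0.291 for antigen presentation, -0.38 for interferon response, -0.203 for inflammatory and complement, -0.118 for ribosomal protein and -0.228 for cholesterol synthesis genes. With males alone, only 3 of them homozygous saline fish, the direction turned for lysosome (0.126), microglia (0.258), antigen presentation (0.418) and interferon genes (1.439). It did not turn for the others.

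Splits of the same fish into groups of the same sizes were counted, 100 for each comparison with the real one included. Chance is argued against for the genotype counts, each reached by 1 of 100 splits, the smallest share that 100 splits can give. These were 246 against a highest other of 3 after saline, 27 against 1 after iron and 847 against 1 for the average. Likewise it is argued against for sex (479 against 3) and for fish numbers above 40 against up to 40 (4201 against 193). For the counts of 0 the splits decide nothing, since 100 of 100 reach 0 whatever the data, and the highest other was 2 for iron in heterozygous fish, 1 in homozygous fish, 1 for their average and 2 for the interaction.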

How the results depend on the processing

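The settings with a spline of fish number, with fish numbers up to 40 or above 40 alone, and without named libraries were chosen after seeing the data. The cause of a change was not tested, except that settings with fewer libraries have fewer fish. No paired analysis was possible because every library is a different fish, replicate numbers only name libraries, and home tank is a term of the model. The correction for GC content and gene length was not run, since the reference used here gives neither. Counts of 0 for iron and for the interaction by edgeR stayed at 0 in every setting run, DESeq2 and voom included, with 662, 287, 376 and 498 genes at an unadjusted p under 0.05 for heterozygous fish, homozygous fish, their average and the interaction. The gene naglu was not called between saline groups in any setting run.

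Between saline groups 246 genes became 494 with DESeq2, 408 with voom, 389 without the tank term, 2237 without sex and tank, 444 with tank as a random block, 397 with a term for fish-number band, 100 with 1 surrogate variable (26 higher, 74 lower), 3 with only the groups compared, 0 with males, 0 with females, 0 with fish up to 40, 0 above 40, 449 without heterozygous saline 5, 376 without heterozygous iron 5 and 586 without both. Counts and agreement without these 2 libraries can rise merely by how they were chosen. With males alone the count between iron groups was 36 (33 higher, 3 lower). Between iron groups 27 became, for DESeq2, voom, no tank, no sex and tank, random block, surrogate variable, only the groups compared, females, spline, up to 40 and above 40, in this order, 141, 229, 116, 107, 178, 72, 1, 0, 76, 0 and 0, and 75, 149 and 196 without heterozygous saline 5, heterozygous iron 5 or both. For the average 847 (399 higher, 448 lower) became 845 with upper quartile factors (466 higher, 379 lower) and 580 with the surrogate variable (206 higher, 374 lower). It became 1677 with voom, 1444 without tank, 2499 without sex and tank, 1705 with the random block, 122 with males, 0 with females, 1 up to 40, 1 above 40, 1421 without heterozygous iron 5 and 1637 without both. For sex 479 became 900 with DESeq2, 1411 with voom, 312 with the band, 121 with the surrogate variable, 0 up to 40, 137 above 40, 263 without heterozygous iron 5 and 285 without both. The correlation of the genotype effects moved from 0.54 to 0.673 without both.

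With an estimated correlation the lists called went from 15, 6, 8, 5, 8, 16, 7 and 21 to 0 in every comparison. By camera at the preset correlation, the 6 lists between genotypes after iron became 10 without tank, 13 with the band, 17 with males, 10 with the spline and 13 without both libraries. For iron in heterozygous fish 8 became 18 without sex and tank, 13 with the spline and 5 without heterozygous saline 10, and in homozygous fish 5 became 13 without sex and tank, 9 without tank, 12 with males and 8 up to 40. For iron averaged 7 became 14 with males, 3 without heterozygous saline 10 and 11 above 40, and for the interaction 8 became 19 without sex and tank, 5 with the band and 13 with males. The estimated correlation ended the calls after saline of lysosome (0.225), myelin (-0.39), microglia (0.618) and interferon genes (1.297), after iron of lysosome (0.16) and myelin genes (-0.298), and of microglia genes for the interaction (-0.494), with medians as they were. The interferon call after saline ended with males (0.389) and above 40 (0.207), and the myelin call after iron up to 40 (-0.078).

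The direction by camera turned with males for the interaction of microglia (0.258), lysosome (0.126), antigen presentation (0.418) and interferon genes (1.439), for iron in homozygous fish of microglia (0.716), ribosomal (0.027) and heat shock genes (0.043), and for iron averaged of ribosomal genes (0.036). Up to 40 it turned after iron for antigen presentation (-0.118) and photoreceptor genes (0.074, by direction of the test and not of the median) between genotypes, for iron in heterozygous fish of astroglia (-0.029) and photoreceptor genes (0.082). Also up to 40 it turned for iron in homozygous fish of heat shock genes (0.068), averaged of microglia (-0.037) and interferon genes (-0.01), and for the interaction of cholesterol genes (0.05). Above 40 it turned for synapse genes between iron groups (0.016), microglia genes for iron in homozygous fish (0.156), immediate early genes for iron averaged (0.012), and the interaction of interferon (0.214) and cholesterol genes (-0.113, by direction of the test alone). Without heterozygous saline 10 it turned for astroglia genes for iron in heterozygous fish (0.01, by direction of the test alone). Among other named genes and lists 3499 values kept their direction and side of the threshold and 882 kept their direction but no longer passed. In counts simulated with the library sizes of these data, 11800000 to 38500000 counts per library, 34% of 1.5-fold interactions were recovered. Depth was not varied, and the simulated genes were independent.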

Other observations

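The tests of scores and the pigment genes below were chosen after the values were seen, and the comparison of sexes was chosen before. Between females and males, with genotype, treatment and tank in the model, 337 genes were higher and 142 lower in females, 479 in all by edgeR. Without the doubted library heterozygous iron 5, a female, 263 were called, and with 1 surrogate variable 121. The coagulation gene f13a1 (ENSDARG00000045453) rose by 2.80 (SE 0.37, edgeR adjusted p = 0.00017), pcyt1bb by 2.43 (SE 0.45) and the myoglobin gene mb by 1.43 (SE 0.24). The steroid enzyme gene hsd17b3 and the deiodinase gene dio2 had log2 fold changes of -1.05 (SE 0.20) and -0.86 (SE 0.18). Of 81 ribosomal protein genes 70 rose and 0 fell, 76 when adjusted over the list alone, among them rpl18 by 0.29 (SE 0.04) and rpl13 by 0.26 (SE 0.04). The list had a median of 0.257, with an adjusted p = 0.178 with an estimated correlation and a fry adjusted p of 0.000553. Of 25 antigen presentation genes 5 rose, 10 when adjusted over the list alone, among them b2m by 0.61 (SE 0.15).

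Means of log2 CPM over list members were compared by permutation, with 10 tests in the family. The myelin score of homozygous less heterozygous fish was -0.33 (n = 10 per group, permutation p = 0.0016, adjusted p = 0.0053) after saline and -0.29 (permutation p = 0.0032, adjusted p = 0.008) after iron, with 10 of 10 homozygous fish below the heterozygous mean each time. The glutamatergic neuron score differed by -0.15 (permutation p = 0.036, adjusted p = 0.06) and -0.10 (permutation p = 0.048, adjusted p = 0.069), neither past the threshold once adjusted. The myelin score less the neuron score differed by -0.19 each time and did not pass (permutation p = 0.16 and 0.076, adjusted p = 0.18 and 0.095). Averaged over both treatments in a linear model with sex and tank, the myelin difference was -0.28 (SE 0.06, t test p = 5.6e-05). With a spline of fish number added to that model it was -0.30 (SE 0.06, t test p = 1.7e-05). The lysosome score differed by 0.39 (permutation p = 2e-05, adjusted p = 2e-04) and 0.20 (permutation p = 0.014, adjusted p = 0.028), after saline and iron. The microglia score differed by 0.76 (permutation p = 0.0012, adjusted p = 0.0053) and 0.09 (permutation p = 0.64, adjusted p = 0.64). After iron the microglia difference was 0.19 without heterozygous iron 5, whose score was high (exact permutation p = 0.28). It ran from 0.00 without homozygous iron 9 to that value when each library was left out in turn. These permutations carry no term for sex or tank, while the saline groups hold 7 and 2 females. The microglia genes had a median of 0.282 for females over males (camera adjusted p = 1.8e-06, adjusted p = 0.481 with an estimated correlation), 0.184 without heterozygous iron 5. With sex and tank in the model the microglia list between saline groups did not pass by fry (adjusted p = 0.065) or with an estimated correlation (adjusted p = 0.362).

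Beside pmelb, a few other genes of pigment cells, not a fixed list and not tested as a group, had mixed values between saline groups. The log2 fold change was 1.75 (SE 0.40, edgeR adjusted p = 0.0188) for tspan10, 1.71 (SE 0.51, adjusted p = 0.0913) for pmela, -0.21 (SE 0.22, adjusted p = 0.67) for oca2 and 0.14 (SE 0.27, adjusted p = 0.842) for slc45a2.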
